A study of Mus musculus with 22 samples.

How the data were processed

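Chromatin immunoprecipitation sequencing (ChIP-seq) was performed in MC3T3-E1 cells, a mouse pre-osteoblastic line that lays down mineralized matrix under osteogenic culture. Per the labels' protocols, undifferentiated cells and cells cultured for 15 days with ascorbic acid and a phosphate source were exposed for 3 h to ethanol vehicle or to 100 nM of calcitriol, the hormonal form of vitamin D, before cross-linking. The antibodies were directed at 4 transcription factors, namely the vitamin D receptor (VDR), its dimerization partner the retinoid X receptor (RXR), C/EBPβ and RUNX2, and at 5 histone modifications (H4K5ac, H3K9ac, H3K4me1, H3K4me3 and H3K36me3). The labels of the samples give H4K5ac, whereas the protocol text names H3K5Ac in its place; the sample labels were followed, and which residue the antibody recognized was not settled. The 22 samples comprise 1 list of regions for each antibody, state and treatment. Vehicle lists were used for VDR and RXR; those of the other antibodies are part of another series and were not analysed here. Passages 5 to 12 were used. Per the labels' protocols, the differentiated cultures were additionally homogenized and spun through sucrose to remove mineralized matrix, a step that undifferentiated cultures did not receive, so preparation and state differ together.

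Reads were processed with Bowtie and HOMER on genome build mm9, per the submitters' processing notes; versions, settings and thresholds are not given in the sources used here. Per the series' design text, biological replicates were made and examined separately. The deposited lists carry region names that count merged peaks, and between 70.4% and 99.6% of the regions in a list were merged from 2 peaks. Each list was therefore read as the overlap of the authors' replicates. No replicate was represented by a list of its own, so the spread between cultures could not be measured. Every deposited file has 6 columns: chromosome, start, end, name, score and strand. The score column of the deposited transcription factor lists held 0 in every region, and each of these regions was 201 bp wide. In the histone lists the score deposited by the authors varied, but what it measures is not given in the sources used here. It was used only to leave out the lowest 25% of regions within a list in 1 alternative. The lists hold no read counts, so sequencing depth is unknown, and a longer list can reflect deeper sequencing, stronger enrichment or more binding.

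Regions on chromosomes 1 to 19 and X were used. Regions on the Y chromosome and the mitochondrial genome were left out of all comparisons and are reported as values only. The lists were placed on the mm9 sequence (NCBIM37) with the GENCODE vM1 annotation, which held 22208 protein-coding genes on these chromosomes. Sites were called shared when they overlapped by at least 1 bp. Shares of sites are given with exact Clopper-Pearson 95% intervals. Overlap between factors was set against 1000 rotations of the sites along their chromosomes, with a one-sided permutation p whose smallest possible value is 0.001. Shares in separate sets of sites were compared with two-sided Fisher's exact tests, with odds ratios and 95% intervals, and Benjamini-Hochberg adjustment within each family of features or gene lists. Sites with RXR but no VDR in the same state served as the background for VDR sites. Histone regions were compared by covered length, and by the Jaccard index, the shared length divided by the length covered in either state. All these intervals and p-values cover the counting of regions only. Regions are not replicates, and the tests compare these lists, not independent cultures.

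Motif matches were searched on both strands in 200 bp around the centre of each site and in 2 flanking windows of the same size, 2 kb to either side. The consensus for the direct repeat with a 3 bp spacer (DR3), the element bound by VDR and RXR, was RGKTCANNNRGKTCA with at most 1 mismatch. The RUNX consensus was TGYGGTY without mismatch, and the C/EBP consensus was TTRCNNAA with at most 1 mismatch. Sites were assigned to genes when their centre lay within 100 kb of any annotated start. The same site could count for several neighbouring genes, and the gene list tests treat such genes as independent. A promoter site lay within 1 kb of a start.

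The comparisons, alternatives and gene lists were chosen before the data were examined. The 11 lists covered vitamin D response, osteoblast transcription factors, bone matrix and mineralization, Wnt, BMP and TGF-beta signalling, osteoclast coupling, adipocyte, chondrocyte, muscle, blood, osteocyte and housekeeping genes. Cebpd and Spi1 were absent from the annotation used, which left 126 genes. The vitamin D and bone matrix lists share 6 genes, and 3 of the osteocyte genes are in the bone matrix list. Genes were named by a rule: up to 25 list members per state with the most VDR sites within 100 kb under calcitriol. A further part of that rule, which ranked peaks by score, could not be applied because these scores were all 0. Genes named outside the rule were chosen after their values were seen and are identified as such.

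Alternatives covered the overlap that counts as shared, the merging of neighbouring sites, random placement within H3K4me1 or H4K5ac regions, gene assignment, motif windows and mismatches, and region number in place of length. Alternatives added after the data had been seen removed VDR sites also called under vehicle, removed sites in H3K4me3 regions, or changed the background. Alternatives that rank sites by score could not be run. The overlap, rotation, motif and Fisher steps were tested on simulated data. With overlap planted at 4200 of 7000 sites in lists of the real VDR and RXR lengths, 4204 were found. Of 200 pairs of unrelated lists of those lengths, 8 had a rotation p at or under 0.05. Of 200 simulated families of features that did not differ between kept and lost VDR sites, 7 gave any call. All 2000 planted DR3 elements were recovered, and 1.10% of 2000 random windows without a planted element held a match. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.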

Results

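ChIP-seq region lists were compared between undifferentiated MC3T3-E1 pre-osteoblasts and the same line after 15 days of osteogenic differentiation. The design asks where VDR binds the genome with calcitriol, which factors and histone marks are found there, and how this changes as the cells become bone-forming. Each of the 22 groups was represented by 1 list, read as the overlap of the authors' replicates. Lists of transcription factor sites held between 274 (VDR, differentiated, vehicle) and 17950 regions (C/EBPβ, undifferentiated, calcitriol), and those of histone marks between 6983 and 53858. There was no replicate check on any difference below; intervals and p-values cover the counting of regions only.

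VDR was found at far more sites with calcitriol than without in undifferentiated cells. The list rose from 937 sites under vehicle to 7000 with calcitriol, a 7.47-fold difference. Of the vehicle sites, 785 (83.8%; 95% interval 81.3 to 86.1) were also called with calcitriol, and 6214 calcitriol sites had no counterpart under vehicle. In differentiated cells the VDR list rose 3.18-fold, from 274 to 871 sites. There, 253 of the 274 vehicle sites (92.3%, 88.5 to 95.2) were also called with calcitriol, and 617 calcitriol sites were not called under vehicle.

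RXR was already widely bound without hormone. In undifferentiated cells its list held 7834 sites under vehicle and 7591 with calcitriol, a ratio of 0.969, yet 2334 of the calcitriol sites were not in the vehicle list and 2565 vehicle sites were not in the calcitriol list. In differentiated cells the RXR list lengthened 1.69-fold with calcitriol, from 4815 to 8126 sites, and 4264 of the vehicle sites (88.6%, 87.6 to 89.4) were retained. The 3853 RXR sites added there exceeded the 617 VDR sites added. Of those added RXR sites, 305 (7.92%, 7.08 to 8.81) carried a called VDR site in the same cells, against 1228 of 2334 (52.6%, 50.6 to 54.7) in undifferentiated cells. RXR sites already present under vehicle carried VDR at shares of 6.34% (5.63 to 7.11) and 56.3% (55.0 to 57.7), so gained sites had VDR slightly more often in differentiated (odds ratio 1.27, two-sided Fisher's exact p = 0.00635) and slightly less often in undifferentiated cells (odds ratio 0.861, 0.781 to 0.949, Fisher's exact p = 0.00292). A VDR site of undifferentiated cells was present at 42.2% of the RXR sites gained in differentiated cells and at 50.9% of those already present there under vehicle, the opposite direction, a difference that was not tested.

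**Figure D1:**
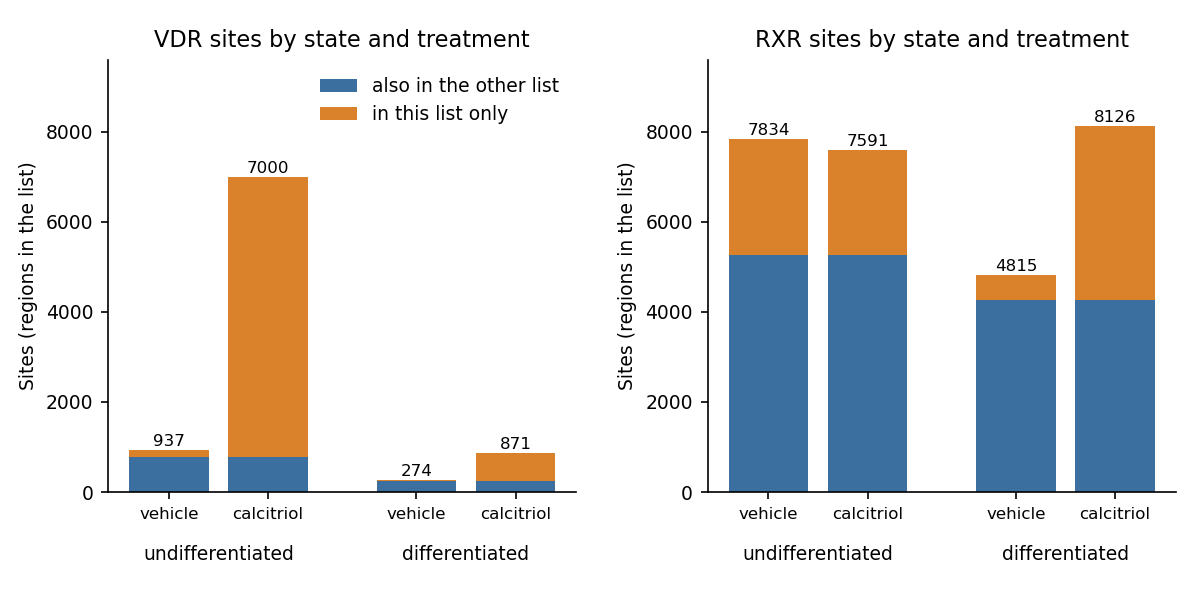
Number of VDR (left) and RXR (right) sites in each list, by state and treatment; blue marks sites also called under the other treatment of the same state and orange marks sites in that list alone. VDR lists lengthen with calcitriol in both states (937 to 7000 and 274 to 871), while the RXR list goes from 7834 to 7591 in undifferentiated and from 4815 to 8126 in differentiated cells.

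The calcitriol-dependent VDR sites carried the element known to bind VDR with RXR more often than sites present under vehicle, which mostly lay at promoters, although most sites of both kinds had no match. In undifferentiated cells a DR3 match was found at 1008 of 6214 calcitriol-only sites (16.2%, 15.3 to 17.2) and at 27 of 786 sites also called under vehicle (3.44%, 2.28 to 4.96), with 1.18% and 1.15% in their flanking windows. The odds ratio between the groups of sites was 0.184 (0.124 to 0.271, two-sided Fisher's exact p = 1.01e-27). In differentiated cells the shares were 206 of 617 (33.4%, 29.7 to 37.3) and 3 of 254 (1.18%, 0.244 to 3.41). VDR vehicle sites lay within 1 kb of a transcription start in 64.2% of cases in undifferentiated and 76.3% in differentiated cells. For calcitriol-only sites the shares were 9.11% and 16.7%. Most VDR sites of undifferentiated cells with calcitriol were distal: 33.5% were intronic and 49.7% intergenic. The DR3 enrichment at VDR vehicle sites of undifferentiated cells (odds ratio against flanks 1.88, Fisher's exact p = 0.0277) was no longer called when exact matches were required (odds ratio 4.02, 1.00 to 16.1, Fisher's exact p = 0.0680, with 6 of 937 sites), and was larger in 100 bp windows (odds ratio 6.49, 2.37 to 17.8, Fisher's exact p = 6.82e-05).

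**Figure D2:**
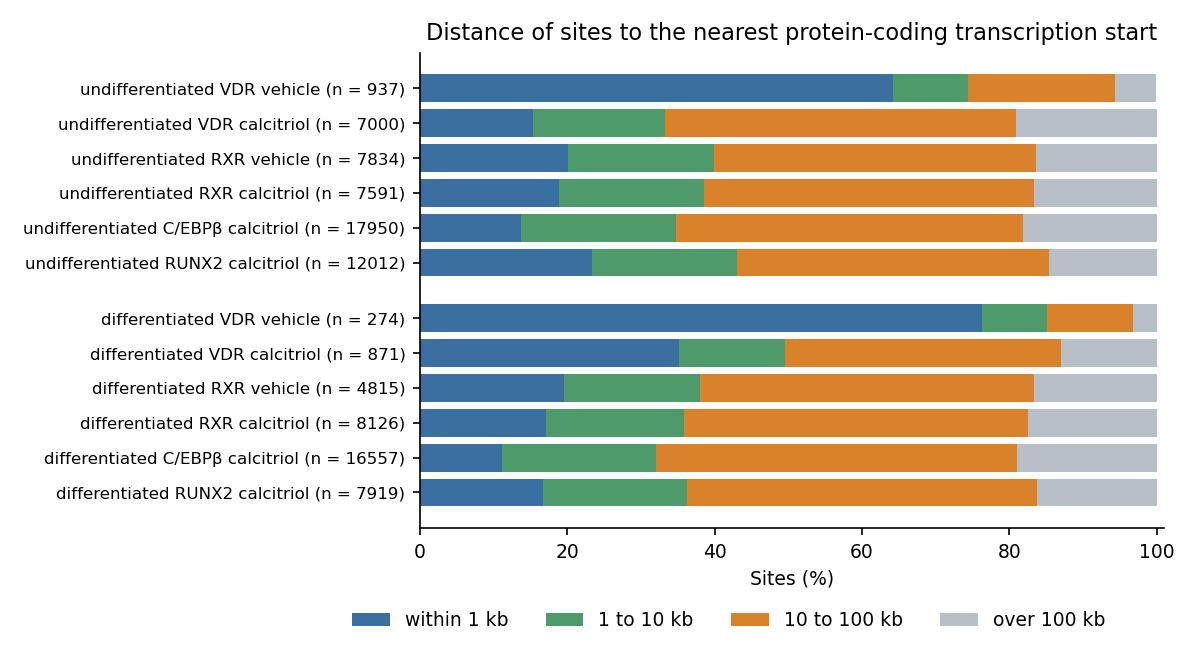
Share of sites (%) by distance to the nearest protein-coding transcription start, for each transcription factor list. VDR sites under vehicle are concentrated within 1 kb of a start (64.2% and 76.3%), and with calcitriol these shares are 15.3% and 35.1%.

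RXR sites followed the same division. Those with a VDR site carried a DR3 match in 11.3% (473 of 4189) of cases in undifferentiated and 31.1% (179 of 576) in differentiated cells with calcitriol. RXR sites without VDR carried it in 1.53% (52 of 3402) and 3.47% (262 of 7550). Against flanking windows the latter were at an odds ratio of 1.17 (0.830 to 1.65; two-sided Fisher's exact p = 0.369) in undifferentiated and 2.98 (2.46 to 3.61; Fisher's exact p = 2.41e-29) in differentiated cells. RXR sites gained with calcitriol carried DR3 in 17.3% of 2334 and 8.38% of 3853 cases. The other factors had their own elements at their sites: a RUNX match at 52.4% and 55.9% of RUNX2 sites (flanks 8.85% and 8.96%), and an exact C/EBP match at 53.2% and 56.4% of C/EBPβ sites (flanks 16.7% and 16.9%), in undifferentiated and differentiated cells in that order. With 1 mismatch the C/EBP consensus matched 98.8% and 99.3% of the C/EBPβ sites and 92.1% and 92.4% of their flanks (odds ratios 7.27, 6.31 to 8.38, and 12.1, 10.0 to 14.6).

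**Figure D3:**
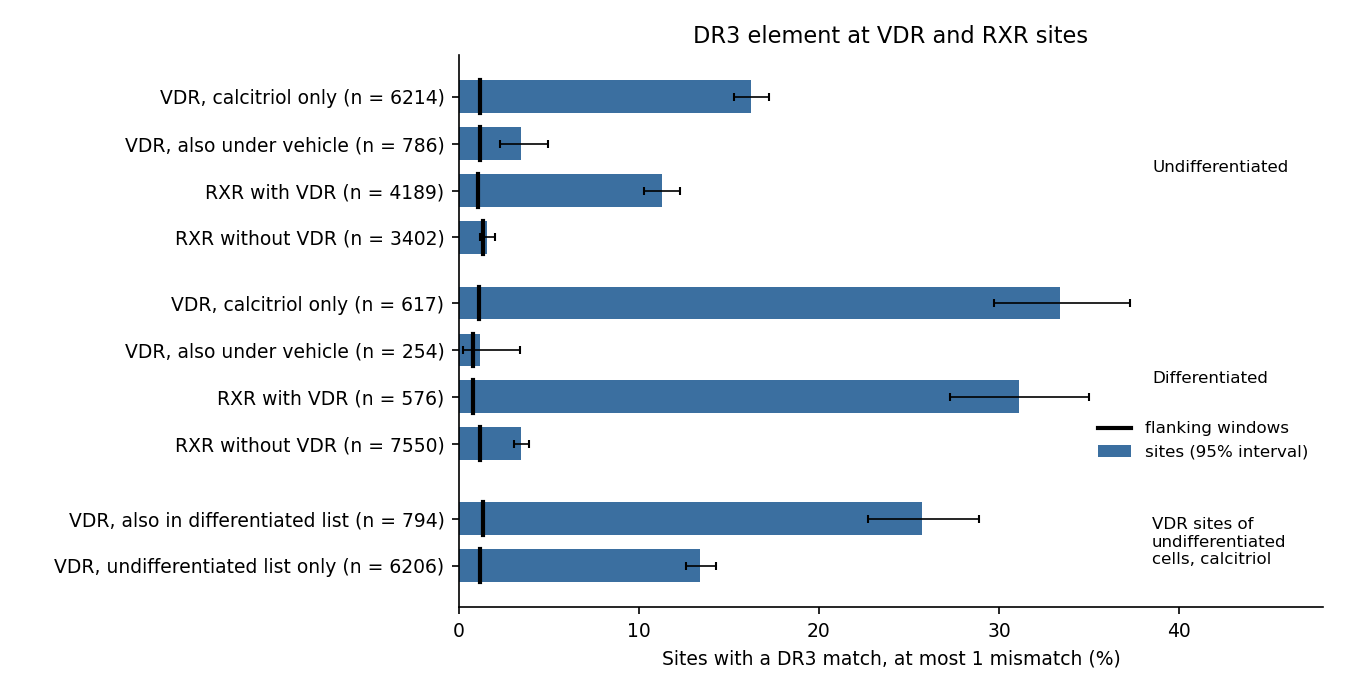
Share of VDR and RXR sites (%) with a DR3 match of at most 1 mismatch, with exact 95% intervals; black ticks give the share in flanking windows. The share is 16.2% and 33.4% at VDR sites called with calcitriol only and 3.44% and 1.18% at those also called under vehicle.

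VDR and RXR shared most of their calcitriol sites from the VDR side in both states. With calcitriol, RXR lay at 4200 of 7000 VDR sites in undifferentiated cells (60.0%, 58.8 to 61.2) and at 575 of 871 in differentiated cells (66.0%, 62.8 to 69.2). Under vehicle the shares were 47.2% (43.9 to 50.4) and 22.6% (17.8 to 28.0). Rotated sites met RXR in at most a mean of 0.143% of cases, and sites placed at random in H3K4me1 or H4K5ac regions, a stricter background, in means between 0.517% and 0.847%. The folds over rotation lay between 278 and 461 and those over placement between 43.8 and 82.6, and each overlap had the smallest permutation p possible, 0.001 (one-sided), against both. From the RXR side, VDR was found at 55.2% (54.1 to 56.3) of RXR sites in undifferentiated and 7.09% (6.54 to 7.67) in differentiated cells with calcitriol.

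The VDR list became far shorter after differentiation, while the partner lists changed less. VDR with calcitriol fell 8.04-fold, from 7000 to 871 sites, and 794 undifferentiated sites (11.3%, 10.6 to 12.1) were called again. Of the differentiated sites, 791 (90.8%, 88.7 to 92.6) were already present in undifferentiated cells and 80 were not. RXR went from 7591 to 8126 sites with 61.6% (60.5 to 62.7) of the undifferentiated sites retained. C/EBPβ, a leucine zipper factor of mesenchymal lineages, went from 17950 to 16557 with 64.7% (64.0 to 65.4) retained. RUNX2, the master regulator of osteoblast commitment, went from 12012 to 7919 with 43.1% (42.3 to 44.0) retained. Without hormone the VDR list was 3.42-fold and the RXR list 1.63-fold longer in undifferentiated cells. Depth, enrichment and the matrix removal step of the differentiated cultures could each alter list length.

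Histone regions of 1 state mostly overlapped regions of the other: 97.0% of H3K4me3 and 96.8% of H3K9ac regions of undifferentiated cells, and 95.8% of H4K5ac and 94.6% of H3K36me3 regions of differentiated cells, overlapped a region of the other state. In the reverse direction these shares lay between 72.1% and 77.4%, and for H3K4me1 they were 86.4% and 83.5%. H3K4me3, a promoter mark, covered 51.3 Mb in undifferentiated and 22.2 Mb in differentiated cells (length ratio 0.433), with mean region widths of 7345 and 2469 bp. Its number of regions moved the other way, from 6983 to 8994 (ratio 1.29). H3K9ac, a mark of active promoters and enhancers, rose from 67.0 to 88.7 Mb. H4K5ac, another acetylation of active chromatin, fell from 340 to 283 Mb. H3K36me3, deposited along transcribed gene bodies, fell from 369 to 323 Mb. H3K4me1, an enhancer mark, was nearly level at 342 and 339 Mb, and its number of regions rose slightly, by a ratio of 1.06. The Jaccard index between states was 0.821 for H3K36me3, 0.720 for H3K4me1, 0.652 for H3K9ac, 0.648 for H4K5ac and 0.330 for H3K4me3, whose shared regions had a median width 2.19 times larger in undifferentiated cells.

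In undifferentiated cells, VDR sites lay together with C/EBPβ and RUNX2 more often than RXR sites without VDR did. C/EBPβ was present at 3089 of 7000 VDR sites (44.1%, 43.0 to 45.3) and at 27.4% (25.9 to 28.9) of 3402 RXR sites without VDR (odds ratio 2.10, 1.92 to 2.29, two-sided Fisher's exact adjusted p = 1.35e-61 over 7 features). RUNX2 was present at 54.0% and 50.5% (odds ratio 1.15, 1.06 to 1.25, Fisher's exact adjusted p = 0.00122). Both factors were found at 30.4% (29.3 to 31.5) of VDR sites, and 20.3% (19.3 to 21.2) had none of RXR, C/EBPβ and RUNX2. VDR sites carried H3K4me3 less often (1399 of 7000 sites against 30.2%; odds ratio 0.576, 0.524 to 0.633, Fisher's exact adjusted p = 1.06e-29) and H3K9ac less often (60.6% against 65.2%; odds ratio 0.820, 0.753 to 0.893, Fisher's exact adjusted p = 1.15e-05). H3K36me3 was more frequent (29.8% against 26.1%; odds ratio 1.20, 1.10 to 1.32, Fisher's exact adjusted p = 1.63e-04). H3K4me1 and H4K5ac covered nearly all sites of both kinds (96.3% and 97.6% of VDR sites), with no called difference. All background sites had RXR, against 4200 of the 7000 VDR sites, so these comparisons mix the presence of VDR with that of RXR. Over all 7591 RXR sites, the 4189 with VDR included, C/EBPβ lay at 40.1% and RUNX2 at 60.8%. RXR sites with VDR thus had both factors more often than RXR sites without VDR (27.4% and 50.5%). For RUNX2 that gap was wider than the 54.0% at all VDR sites shows. These differences were not tested, and the marks were not compared in this way.

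In differentiated cells, C/EBPβ lay at 267 of 871 VDR sites (30.7%, 27.6 to 33.8) and RUNX2 at 292 (33.5%, 30.4 to 36.8), below the 38.9% and 44.2% of 7550 RXR sites without VDR (odds ratios 0.695, 0.597 to 0.809, and 0.637, 0.550 to 0.739; Fisher's exact adjusted p = 3.34e-06 and 3.37e-09). H3K4me3 was more frequent at VDR sites (305 of 871 against 16.0%; odds ratio 2.83, 2.43 to 3.29, Fisher's exact adjusted p = 1.24e-36), and H3K4me1 (93.2% against 98.7%; odds ratio 0.183, 0.131 to 0.254, Fisher's exact adjusted p = 2.79e-19) and H4K5ac (94.0% against 96.5%; odds ratio 0.571, 0.420 to 0.775, Fisher's exact adjusted p = 8.98e-04) were less frequent. The lower H3K4me1 and H4K5ac shares came largely from the 80 VDR sites called in differentiated cells alone, a split chosen after the data had been seen. These had the marks at 51.2% and 60.0%, whereas the 794 undifferentiated VDR sites called again had each mark at 97.5% in differentiated cells. That is above the H4K5ac background and slightly below the H3K4me1 background. H3K9ac and H3K36me3 did not pass the test. Several of these calls were not made when VDR sites already present under vehicle were left out. The odds ratios were then 1.03 for C/EBPβ, 0.810 for RUNX2, 0.858 for H4K5ac and 0.967 for H3K4me3, none of them called. With RXR sites lacking VDR in both states as the background, C/EBPβ (0.898), RUNX2 (0.932) and H4K5ac (0.889) were not called, and H3K9ac was called as more frequent (1.63). All background sites had RXR, against 575 of the 871 VDR sites. A lower share at VDR sites can therefore reflect the VDR sites without RXR. Over all 8126 RXR sites, the 576 with VDR included, C/EBPβ lay at 39.1% and RUNX2 at 44.1%. RXR sites with VDR thus had C/EBPβ more often than RXR sites without VDR (38.9%), and RUNX2 slightly less often (44.2%). These differences were not tested, and for the marks VDR sites with RXR were not compared on their own.

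**Figure D4:**
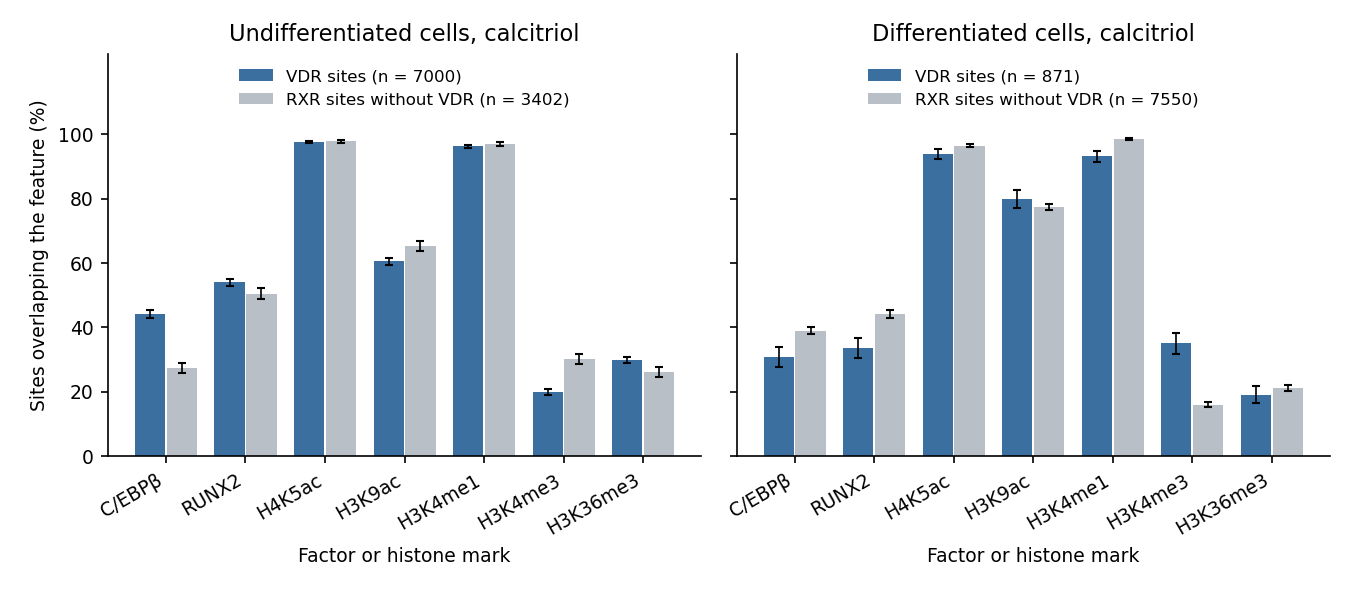
Share of VDR sites (blue) and RXR sites without VDR (grey) that overlap each factor or histone mark with calcitriol (%), by state, with exact 95% intervals from counting. C/EBPβ lies at 44.1% of VDR sites in undifferentiated and 30.7% in differentiated cells, against 27.4% and 38.9% of RXR sites without VDR.

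RUNX2 and C/EBPβ also met each other. Over all sites, those with VDR included, C/EBPβ was found at 33.4% (32.6 to 34.3) of RUNX2 sites in undifferentiated and 35.6% (34.5 to 36.6) in differentiated cells, and RUNX2 at 22.6% (22.0 to 23.3) and 17.1% (16.6 to 17.7) of C/EBPβ sites. Rotated sites overlapped in at most a mean of 0.300% of cases and sites placed in H3K4me1 or H4K5ac regions in at most 1.64% (permutation p = 0.001 for each, one-sided, the smallest possible). At sites without VDR the shares were lower, in a split chosen after the data had been seen: C/EBPβ lay at 23.3% (22.4 to 24.2) of 8232 RUNX2 sites without and 55.5% (53.9 to 57.1) of 3780 with VDR in undifferentiated cells, and at 34.9% of 7625 and 53.4% of 294 in differentiated cells.

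VDR sites kept after differentiation more often had VDR under vehicle, RXR with calcitriol and a DR3 element than lost sites did, although most kept sites lacked a vehicle call and most lacked a DR3. Of the 794 kept sites, 44.3% (40.8 to 47.9) were also called under vehicle in undifferentiated cells, against 6.99% (6.37 to 7.66) of the 6206 sites not called again (odds ratio 10.6, 8.93 to 12.6, two-sided Fisher's exact adjusted p = 9.63e-149 over 20 features). RXR was present with calcitriol in differentiated cells at 70.2% (66.8 to 73.3) of kept and 52.3% (51.1 to 53.6) of lost sites (odds ratio 2.14, 1.83 to 2.51, Fisher's exact adjusted p = 2.62e-21). RXR under vehicle in undifferentiated cells went the other way, at 39.7% (36.3 to 43.2) of kept and 50.5% (49.3 to 51.8) of lost sites (odds ratio 0.643, 0.553 to 0.748, Fisher's exact adjusted p = 1.86e-08). A DR3 match was found at 25.7% (22.7 to 28.9) of kept and 13.4% (12.6 to 14.3) of lost sites (odds ratio 2.24, 1.88 to 2.66, Fisher's exact adjusted p = 4.60e-17). The vehicle call and the DR3 marked mostly different kept sites. Of the 786 sites also called under vehicle 352 were kept and 27 held a DR3, so at most 27 of the 204 kept sites with a DR3 were vehicle sites. Of the 6214 calcitriol-only sites 442 were kept, and their DR3 share was above the 25.7% of all kept sites. Of the kept sites 37.4% (34.0 to 40.9) lay within 1 kb of a start, against 12.5% (11.7 to 13.4) of the lost sites. RUNX2 of undifferentiated cells was less frequent at kept sites (46.2% against 54.9%; odds ratio 0.705, 0.608 to 0.817, Fisher's exact adjusted p = 7.69e-06).

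Several of the mark and C/EBPβ differences between kept and lost sites changed when the promoter-rich sites called under vehicle were left out. C/EBPβ of undifferentiated cells was less frequent at kept sites (odds ratio 0.809, 0.696 to 0.940, Fisher's exact adjusted p = 0.0104). When the sites called under vehicle were left out, which left 442 kept and 5772 lost sites, it was more frequent (odds ratio 1.34, 1.11 to 1.63, Fisher's exact adjusted p = 0.00797), and outside H3K4me3 regions the odds ratio was 1.11. Without vehicle sites, C/EBPβ of differentiated cells went from an odds ratio of 0.966 to 1.47, now called. H3K4me3 of differentiated cells turned from 4.29 (3.64 to 5.05) to 0.626, and H3K4me3 of undifferentiated cells (2.68) and H3K9ac of undifferentiated (1.95) and of differentiated cells (1.99) were no longer called (1.01, 0.973 and 1.10). H4K5ac of differentiated cells was no longer called either, but its odds ratio of 1.75 (1.03 to 2.96) stayed within the interval of the full set (2.31, 1.46 to 3.64), with fewer kept sites.

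VDR sites of undifferentiated cells were frequent near genes of the bone matrix and of the vitamin D response. A VDR site with calcitriol lay within 100 kb of a start for 22 of 24 bone matrix and mineralization genes, against 40.9% of all 22208 genes (odds ratio 15.9, 3.75 to 67.8, two-sided Fisher's exact adjusted p = 3.18e-06 over 11 lists). Spp1, which encodes the matrix protein osteopontin, had 11 VDR sites, the small proteoglycan gene Dcn 10, the type I collagen gene Col1a2 8, Mepe 6 and the bone sialoprotein gene Ibsp 5. Spp1, Mepe and Ibsp lie in 1 region of 338 kb with 13 such sites, so their counts overlap. Of 33 vitamin D response genes 24 had a VDR site (odds ratio 3.86, 1.79 to 8.31, Fisher's exact adjusted p = 0.00149), among them Lrp5, a Wnt co-receptor, and the growth factor binding protein gene Igfbp5 with 8 each, Thbd with 7 and Vdr itself with 5. With genes that have an RXR site within 100 kb as the background, neither list was called: 19 of 22 vitamin D response genes (odds ratio 2.09, Fisher's exact adjusted p = 0.940) and 20 of 20 bone matrix genes (Fisher's exact adjusted p = 0.0766) had a VDR site, against 75.2% of 9739 genes. The bone matrix odds ratio there, 13.5 (0.818 to 224), rests on a correction for an empty cell.

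In differentiated cells the vitamin D response genes were called and the bone matrix genes were not, a contrast between the lists that was not tested. Of the vitamin D response genes 14 of 33 had a VDR site, against 12.1% of all genes (odds ratio 5.35, 2.68 to 10.7, two-sided Fisher's exact adjusted p = 1.38e-04 over 11 lists), with Spp1 at 4 sites, and Cbs, Igfbp5 and the collagenase gene Mmp13 at 2 each. That call held with the RXR background (13 of 20 genes against 21.8%; odds ratio 6.70, 2.67 to 16.8, Fisher's exact adjusted p = 4.30e-04). The change of each list between states was not part of these tests. Bone matrix genes with a site numbered 5 of 24 (odds ratio 1.91, 0.711 to 5.11, Fisher's exact adjusted p = 0.559), namely Spp1, Mmp13, Mepe, Sparc and, named outside the rule after its values were seen, Enpp1. The odds ratio was larger, and still not called, with each site at its nearest start (4.02, 1.20 to 13.5, Fisher's exact adjusted p = 0.195), at 20 kb (3.58, 1.07 to 12.0, Fisher's exact adjusted p = 0.231) and without vehicle sites (3.55, 1.32 to 9.53, Fisher's exact adjusted p = 0.121). With the RXR background the difference was small: 5 of 21 bone matrix genes (23.8%) had a VDR site, against 21.8%. The differentiated site of Mepe, starting at 104837019, was also counted for Spp1. No VDR site was called in differentiated cells within 100 kb of Dcn, Col1a2, Col1a1, Ibsp, Lox or Col5a1, which had between 4 and 10 sites in undifferentiated cells. Of the 86 list members with a VDR site in undifferentiated cells, 27 had a site in differentiated cells, and no member had one in differentiated cells only.

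The osteoblast transcription factors and the Wnt, BMP and TGF-beta genes were not called at 100 kb. In undifferentiated cells 12 of 18 transcription factor genes (odds ratio 2.89, 1.09 to 7.71, two-sided Fisher's exact adjusted p = 0.0857) and 16 of 25 signalling genes (odds ratio 2.57, 1.14 to 5.82, Fisher's exact adjusted p = 0.0857) had a VDR site, including Cebpb with 9, Fosl2 with 7, Lrp6 with 6, and Axin2 and Tgfb2 with 5 each. When each site was assigned to its nearest start only, both lists were called (odds ratios 5.31 and 7.99), as were the 6 osteoclast coupling genes (10.6), and at 20 kb (3.08) and without sites called under vehicle (2.95, Fisher's exact adjusted p = 0.0346) the signalling genes were. In differentiated cells the counts were 5 of 18 (odds ratio 2.79, Fisher's exact adjusted p = 0.213), with Fosl1, Fosl2, Junb, Sp7 and Cebpb, and 3 of 25 (odds ratio 0.986, Fisher's exact adjusted p = 1.00), with Lrp5, Lrp6 and Sfrp2. Fosl1, Junb and Sp7 had as many VDR sites under vehicle in differentiated cells. Without sites called under vehicle, 2 of 18 transcription factor genes had a VDR site there.

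The smaller lists were not called at 100 kb in either state. In undifferentiated cells VDR sites were found near 4 of 6 osteoclast coupling genes, with 11 at Csf1 and 6 at Tnfsf11 (5 under vehicle), which encode cytokines that drive osteoclast formation, and near 5 of 7 adipocyte, 3 of 6 chondrocyte, 2 of 5 muscle, 2 of 3 blood and 2 of 6 osteocyte genes (odds ratios 2.89, 3.61, 1.45, 0.964, 2.89 and 0.723; Fisher's exact adjusted p between 0.287 and 1.00). In differentiated cells 1 osteoclast coupling gene (Csf1), 1 osteocyte gene (Mepe) and none of the adipocyte, chondrocyte, muscle and blood genes had a site (Fisher's exact adjusted p between 0.990 and 1.00). Of the 6 housekeeping genes 3 had VDR sites in both states, namely Actb, Rplp0 and Tbp (odds ratios 1.45 and 7.24; Fisher's exact adjusted p = 0.848 and 0.148). Actb had 17 sites in undifferentiated cells, more than any other list member, and 5 under vehicle. Under vehicle no list was called in either state (lowest Fisher's exact adjusted p = 0.295 over 11 lists, for 6 of 18 osteoblast transcription factors, odds ratio 2.68, and for 3 of 6 housekeeping genes, odds ratio 5.36).

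Some of the VDR sites closest to a start of these genes held a DR3 element. The site closest to Lrp5 (chr19:3685814-3686014, mm9, promoter) held the exact DR3 GGGTCACTGGGGTCA at 3685884-3685898 and had no RXR site in either state. The same 15 bp occurred at 167493614-167493628 in the site closest to Cebpb (chr2:167493491-167493691, mm9), 20.8 kb upstream and within an intron, where no other factor and none of the 5 histone marks was called in either state. These 15 bp occurred 25 times on the chromosomes used, and the pair of sites shared a longest run of 16 bp. No repeat annotation was used, so repeats at these sites were not excluded. The closest site of Sparc, which encodes the matrix protein osteonectin (chr11:55219471-55219671, mm9, intronic), held GGTTCAAAGGGTTCA, overlapped RXR in both states and was also called for VDR in differentiated cells. At Mmp13 the closest site lay 10.4 kb upstream (chr9:7262013-7262213, mm9, intergenic), held AGGTGAGCGGGTTCA with 1 mismatch, and was called in both states. The closest site of the AP-1 gene Junb (chr8:87508861-87509061, mm9, intergenic) held AGGCCATGGGGTTCA with 1 mismatch. Cyp24a1, which encodes the enzyme that inactivates calcitriol, was chosen after its values were seen: it had 3 VDR sites in undifferentiated cells and none in differentiated cells, the closest 0.263 kb upstream of its start (chr2:170322808-170323008, mm9) with RXR and C/EBPβ in undifferentiated cells and none of the histone marks.

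Across the cluster of mineralized-tissue genes on chromosome 5, VDR sites became fewer after differentiation while RXR, C/EBPβ and RUNX2 sites remained numerous. In the region chr5:104581632-104920069 (mm9; 338 kb), which holds Dmp1 (named outside the rule, for its place in the region), Ibsp, Mepe and Spp1, VDR sites went from 2 to 13 with calcitriol in undifferentiated and from 0 to 4 in differentiated cells. The differentiated VDR sites started at 104837019, 104862062, 104863283 and 104863964, upstream of or at the Spp1 start (104864137). RXR sites numbered 13 and 16 with calcitriol, C/EBPβ sites 20 and 23, and RUNX2 sites 12 and 10, in undifferentiated and differentiated cells in that order.

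**Figure D5:**
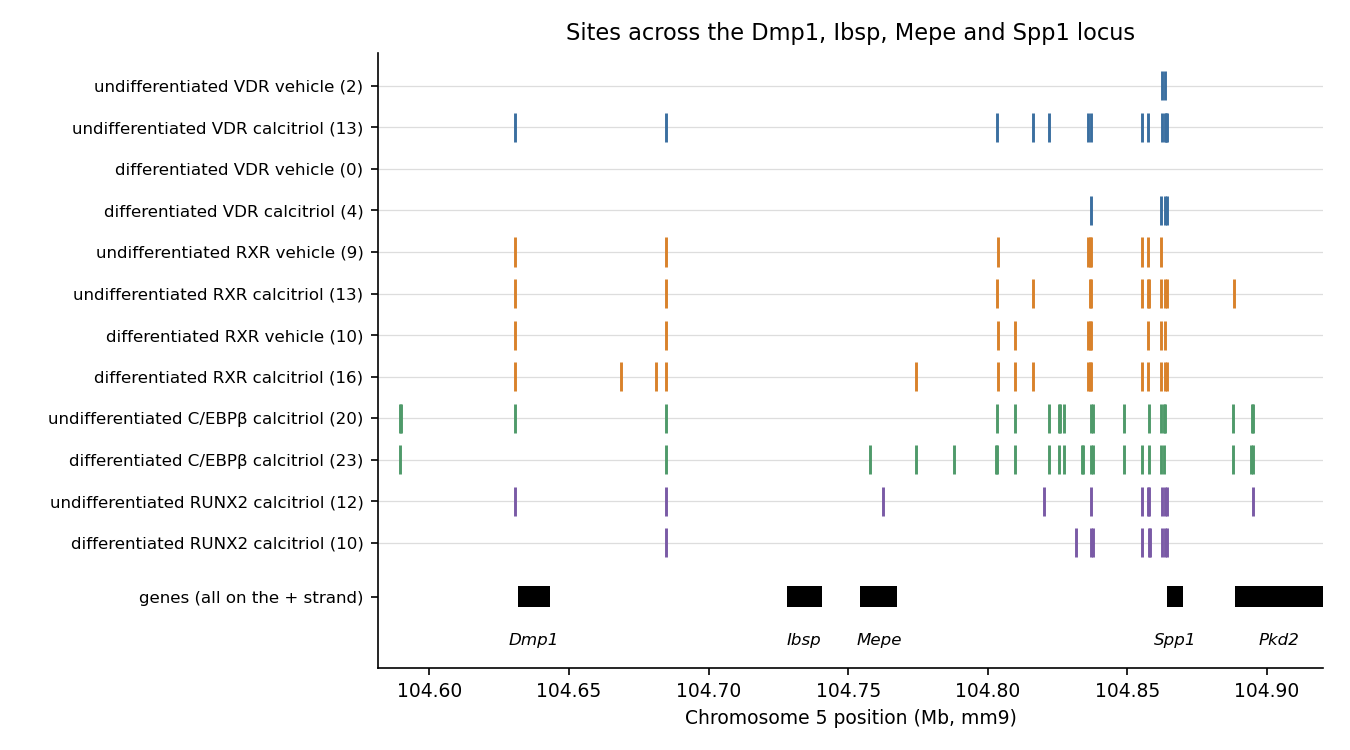
Positions of transcription factor sites across the gene cluster on chromosome 5 (Mb, mm9); each vertical line is 1 site, with the number of sites per list in parentheses, and black boxes are genes. With calcitriol, VDR has 13 sites in undifferentiated and 4 in differentiated cells, while RXR has 13 and 16.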

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

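In this part, the tests of homogeneity between states, the split of missing sites by DR3 and the RXR, H3K4me1 and H3K9ac shares of missing sites were chosen after the results had been seen. The RXR list length ratio of calcitriol over vehicle was 0.969 in undifferentiated and 1.69 in differentiated cells, opposite directions whose difference was not tested for lack of separate replicates. The odds ratio of a feature at VDR sites against RXR sites without VDR differed between states for all 7 features (chi-square tests of homogeneity, adjusted over 7). The ratio of the odds ratios, undifferentiated over differentiated, was 3.02 for C/EBPβ (chi-square adjusted p = 2.21e-34), 1.80 for RUNX2 (chi-square adjusted p = 1.36e-11), 4.50 for H3K4me1 (chi-square adjusted p = 5.95e-13) and 1.36 for H3K36me3 (chi-square adjusted p = 0.00281). It was 0.204 for H3K4me3 (chi-square adjusted p = 2.36e-67), 0.704 for H3K9ac (chi-square adjusted p = 5.48e-04) and 1.56 for H4K5ac (chi-square adjusted p = 0.0354). The background in differentiated cells holds sites that had VDR in undifferentiated cells, and several of the odds ratios behind these values changed when VDR sites called under vehicle were left out. The states also share sites: 791 of the 871 differentiated VDR sites were present in undifferentiated cells. The chi-square tests treat the states as independent sets, so their p-values do not allow for this sharing. All background sites had RXR, unlike the VDR sites. The differentiated odds ratios of H3K4me1 and H4K5ac rest largely on the 80 VDR sites called there alone, with the marks at 51.2% and 60.0%. At the 794 VDR sites of both states each mark lay at 97.5%.

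Regions outside the chromosomes used were present above the limit of 3 that a count of 0 allows in several lists without a vehicle control. On the Y chromosome C/EBPβ had 4 regions in undifferentiated and 5 in differentiated cells, and H3K9ac had 6 and 4. H4K5ac had 5 and H3K36me3 had 7 there in undifferentiated cells, and H3K4me3 had 5 in differentiated cells. RUNX2 had 11 regions on the mitochondrial genome in undifferentiated cells, of 12023 deposited. The VDR lists had 10 regions on the Y chromosome under vehicle and 7 with calcitriol in undifferentiated cells, so calcitriol was not above vehicle there.

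The VDR list of differentiated cells with calcitriol was 8.04-fold shorter than that of undifferentiated cells. The tables argue against all of the missing sites lacking VDR elements, since the odds ratio of a DR3 match against flanks was 13.2 (Fisher's exact p = 4.54e-261). A match was found at 831 of the 6206 missing sites (13.4%), so indirect binding at the others stays open. Closing of the chromatin as the whole cause is also argued against. With calcitriol in differentiated cells, RXR was bound at 52.3% (51.1 to 53.6) of the missing sites. It was bound at 1366 of the 6829 RUNX2 sites that were lost. These had less RXR in undifferentiated cells (28.4%, against 59.0% of the missing VDR sites), so that contrast says nothing on closing. Closing stays open at the 2960 missing sites without RXR in differentiated cells. Of these 92.4% lay in an H3K4me1 region of differentiated cells, but so did 97.6% of RXR and 97.9% of RUNX2 sites that were lost, so this share is too near its ceiling to decide. H3K9ac rose at them from 49.9% to 58.8%, but it also rose at lost RXR and RUNX2 sites and covered more of the genome in differentiated cells, with unknown depth. Weaker VDR immunoprecipitation or calling stays open: missing sites without RXR under vehicle gained RXR with calcitriol in differentiated cells in 31.9% of 4216 cases, against 26.4% of 2268 RXR sites without VDR (odds ratio 1.31, 1.17 to 1.47, Fisher's exact p = 2.73e-06), and in 48.2% of 1968 cases among missing sites that, like that background, had RXR in undifferentiated cells (odds ratio 2.60, 2.28 to 2.95), as that explanation requires. RXR sites without a called VDR site held DR3 above flanks in differentiated cells (odds ratio 2.98) but not in undifferentiated cells (1.17, 0.830 to 1.65), which missed VDR calls could also give. What keeps it from being settled is that missing sites with a DR3 gained RXR less often (18.6% of 780) than those without (35.0% of 3436). Kept DR3 sites gained RXR in 88.3% of 154 cases. In undifferentiated cells the shares at missing sites with and without a DR3 were 32.5% of 750 and 31.9% of 2319. Those are different subsets, chosen for lacking vehicle RXR in undifferentiated cells. The matrix removal step, made on differentiated cultures alone, and a biological loss of VDR binding in the differentiated state both remain open and untested.

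VDR sites called under vehicle lay within 1 kb of a start far more often than those called with calcitriol only. Signal at promoters without a VDR element, nonspecific or indirect, had the low DR3 share it requires: 3.44% at sites also called under vehicle against 16.2% at the others (odds ratio 0.184, 0.124 to 0.271). The share in their flanking windows was 1.15% (odds ratio 3.07, 1.68 to 5.61, Fisher's exact p = 3.13e-04), so some of these sites may bind VDR directly. No immunoprecipitation control list was used here, and no biological explanation was tested.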

How the results depend on the processing

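The alternatives that leave out VDR sites called under vehicle or sites in H3K4me3 regions, and those with a changed background, were chosen after the data had been seen. Of 345 recomputed values, 262 were counted as unchanged, 22 moved further, 13 were no longer called, 8 became called and 40 changed direction. Unchanged values kept their direction and side of the threshold or, for shares, moved within their interval. Ratios of list length or covered length have no interval. They counted as unchanged when they stayed on the same side of 1 and within 1.5-fold of the main value. The cause was not tested for any of the changes. All values were among these 262 with motif windows of 100 bp (12 of 12), centres within 200 bp (60 of 60), merging of sites within 100 bp (24 of 24) or of histone regions within 1000 bp (5 of 5), or removal of the lowest 25% of histone scores (5 of 5). For odds ratios this covers direction and threshold only. In 100 bp windows the DR3 odds ratio at undifferentiated VDR vehicle sites went from 1.88 to 6.49. With placement in H3K4me1 or H4K5ac regions all 10 overlaps kept the smallest p, but their folds fell from between 112 and 461 to between 18.8 and 82.6. For equally wide transcription factor sites the 200 bp rule is the same as 1 bp of overlap, so it tests nothing there. Alternatives that rank transcription factor sites by score (the top 50%, equal list lengths, a score-matched RXR background and tests within score strata) were not run because those scores are all 0. No paired analysis was possible because each group holds 1 list. Depth limits all list lengths, and it is unknown.

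With 50% of the shorter region required, shared shares fell to 10.5% for VDR calcitriol sites in the vehicle list of undifferentiated cells, 64.2% and 50.1% for RXR calcitriol sites in the vehicle lists, and, between states, 57.6% for RXR, 63.3% for C/EBPβ and 40.0% for RUNX2. RXR lay at 38.8% of undifferentiated vehicle, 55.3% of undifferentiated calcitriol and 62.7% of differentiated calcitriol VDR sites, C/EBPβ at 32.4% and 22.3%, RUNX2 at 46.1% and 27.0%, and C/EBPβ at 24.1% and 28.0% of RUNX2 sites. The kept against lost odds ratio of C/EBPβ was 0.848 in undifferentiated cells, no longer called, and 1.01 in differentiated cells. By number of regions, the ratio between states was 1.06 for H3K4me1 and 1.29 for H3K4me3. With exact motif matches the DR3 odds ratio was 1.09 at undifferentiated RXR vehicle sites and 4.02 at undifferentiated VDR vehicle sites, neither called, and 0.665 at differentiated VDR vehicle sites (0 of 274 sites).

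Against RXR sites without VDR, leaving out vehicle sites gave odds ratios in differentiated cells of 1.03 for C/EBPβ, 0.810 for RUNX2, 0.858 for H4K5ac, 0.982 for H3K9ac and 0.967 for H3K4me3. With RXR sites lacking VDR in either state these were 0.898 for C/EBPβ, 0.932 for RUNX2, 0.889 for H4K5ac and 1.63 for H3K9ac, the last one called. For kept against lost sites, leaving out vehicle sites gave 1.34 for C/EBPβ, 0.973 for H3K9ac and 1.01 for H3K4me3 of undifferentiated cells, and 1.47 for C/EBPβ, 1.17 for RUNX2, 1.75 for H4K5ac, 1.10 for H3K9ac and 0.626 for H3K4me3 of differentiated cells. Outside H3K4me3 regions the values were 1.11 for C/EBPβ, 0.971 for H4K5ac and 0.979 for H3K4me1 of undifferentiated cells, and 1.32 for C/EBPβ, 1.20 for RUNX2, 1.35 for RXR under vehicle and 2.02 for H3K4me1 of differentiated cells, the last 2 called.

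For gene lists the values are odds ratios. With each site at its nearest start, undifferentiated cells gave 5.31 for osteoblast transcription factors and 7.99 for signalling genes, both called, 1.33 for muscle, 0.757 for blood (0 of 3) and 2.65 for osteocyte genes. Differentiated cells gave 3.84 for signalling and 5.62 for chondrocyte genes. They had no site at the transcription factors (0 of 18; 0.757), osteoclast coupling (0 of 6; 2.16) and osteocyte genes (0 of 6; 2.16), against 3.44% of all genes. At 20 kb, undifferentiated cells gave 3.08 for signalling (called), 0.911 for adipocyte, 1.37 for muscle, 0.781 for blood (0 of 3) and 1.09 for osteocyte genes. Differentiated cells gave 2.18 for signalling genes and had no site at the transcription factors (0 of 18; 0.675), osteoclast coupling (0 of 6; 1.92) and osteocyte genes (0 of 6; 1.92), against 3.85% of all genes. With the RXR background, undifferentiated vitamin D response (2.09) and bone matrix genes (13.5; 20 of 20) were no longer called, osteoclast coupling and chondrocyte genes gave 0.988 and 0.988, muscle genes had a share above the background (1 of 1 against 75.2%; 0.988), and differentiated signalling and osteoclast coupling genes gave 1.08 and 0.898. Without vehicle sites, signalling genes gave 2.95 in undifferentiated cells (called) and 1.84 in differentiated cells, and housekeeping genes 0.392 in undifferentiated cells. Where a list had sites at none or all of its members, the odds ratio comes from a correction for empty cells and can point the wrong way, so the raw shares gave the direction.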

Other observations

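In this part the comparisons of site classes and of marks at starts, the test of kept gene lists and the H3K4me3 widths were chosen after the results had been seen, while the gene list tests of RXR, C/EBPβ and RUNX2 were planned. Intervals cover counting only. RUNX2 sites of undifferentiated cells alone lay within 1 kb of a start in 26.2% of 6829 cases (25.2 to 27.3), those of differentiated cells alone in 11.2% of 2733 (10.0 to 12.4), and those of both states in 19.6% of 5183 (18.5 to 20.7). For C/EBPβ the shares were 13.4% (12.6 to 14.3), 4.56% (4.00 to 5.18) and 13.9% (13.3 to 14.5), so sites of undifferentiated cells alone and of both states were alike within counting intervals. RUNX2 sites of both states held a RUNX match more often (59.0%, 57.6 to 60.3) than sites of undifferentiated (47.4%, 46.2 to 48.6) or differentiated cells alone (50.1%, 48.2 to 51.9). H3K9ac was more frequent in differentiated than in undifferentiated cells at C/EBPβ, RUNX2 and RXR sites of every class, not only where binding was gained. At sites bound in differentiated cells alone it lay at 1620 against 942 of 4955 C/EBPβ sites, 50.7% against 33.9% of RUNX2 and 64.0% against 46.3% of RXR sites. At sites bound in undifferentiated cells alone the shares were, in the same order, 47.7% against 40.9%, 72.0% against 59.6% and 73.4% against 58.5%, and at sites of both states 59.5% against 46.3%, 81.3% against 64.1% and 87.9% against 70.3%. VDR sites of differentiated cells alone went the other way, with H3K9ac at 29 of 80 in differentiated against 41 in undifferentiated cells, while it rose at VDR sites of undifferentiated cells alone (58.9% to 73.1%) and of both states (73.7% to 84.4%). H3K9ac regions covered more of the genome in differentiated cells at large, and none of these differences was tested.

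At gene starts, H3K4me3 was called for 7797 protein-coding genes in undifferentiated and 9426 in differentiated cells, with 7501 in both. The genes named at starts were chosen after their values were seen, and most lie outside the rule for named genes. Among list members, Dcn, Ogn and Phospho1 of the bone matrix and Lef1 and Tcf7 of the transcription factors had H3K4me3 at a start in differentiated cells alone. So did Atp2b1, Grem1, Pdpn and the housekeeping gene Hprt, and 1925 of all genes. Cebpb, Fosl1, Twist2 and the chondrocyte gene Col2a1 had it in undifferentiated cells alone, as did 296 of all genes. In differentiated cells alone, H3K9ac was called at Alpl, which encodes the phosphatase of mineralization, and at Dlx3, Nog and Enpp3 (464 of all genes). H3K36me3 was called in differentiated cells alone at Sp7, an osteoblast transcription factor, and at Tcf7 and Phospho1 (194 of all genes). H3K4me1 was called at Sost and Mepe, genes of the osteocyte list, in differentiated cells alone (960 of all genes). The same held for Dkk1, Sfrp2, Fosl2, Jun, Msx1, Msx2, Cbs, Enpp1, the muscle gene Des and the housekeeping gene Hprt. H4K5ac was called in differentiated cells alone at Msx1, Tcf7 and the adipocyte genes Adipoq and Lpl (358 of all genes). In undifferentiated cells alone H3K36me3 was called at Ogn, Bmp4, Slc8a1, Acta2 and Rplp0 (687 of all genes). H3K4me1 was called there alone at Fn1, Tnfsf11, Fabp4 and Csf1r (359 of all genes), and H4K5ac at Twist2, Cbs, Pparg and Csf1r (398 of all genes). These differences in marks were not tested. Of the genes with a VDR site in undifferentiated cells, 29.1% of 9082 also had 1 in differentiated cells, against 14 of 24 vitamin D response genes (odds ratio 3.42, 1.52 to 7.71, two-sided Fisher's exact adjusted p = 0.0319 over 11 lists) and 5 of 22 bone matrix genes (odds ratio 0.715, Fisher's exact adjusted p = 0.882). Genes with more sites have more chances to keep 1, which this test leaves out.

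The 80 VDR sites of differentiated cells alone stood apart from the kept sites: 7.50% (2.80 to 15.6) held a DR3 match, 26.2% (17.0 to 37.3) overlapped RXR and 51.2% (39.8 to 62.6) lay in an H3K4me1 region of differentiated cells, against 25.7%, 70.2% and 97.5% of the 794 sites of both states.

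The bone matrix list was called for every list of RXR, C/EBPβ and RUNX2, and other lists for some of them. RXR with calcitriol had a site within 100 kb of 20 of 24 bone matrix genes in undifferentiated and 21 of 24 in differentiated cells (odds ratios 6.41 and 9.01, Fisher's exact adjusted p = 0.00114 and 1.38e-04 over 11 lists). For C/EBPβ the counts were 24 and 23 (odds ratios 25.4 and 14.6, Fisher's exact adjusted p = 0.00105 and 0.00206) and for RUNX2 24 and 22 (odds ratios 33.2 and 12.7, Fisher's exact adjusted p = 7.19e-05 and 4.88e-05). Vitamin D response genes were called for undifferentiated RXR under vehicle and with calcitriol (Fisher's exact adjusted p = 0.00174 and 0.0466) and for C/EBPβ in undifferentiated and differentiated cells (0.00799 and 0.0222). Signalling genes were called for undifferentiated RXR under vehicle and with calcitriol (0.00693 and 0.00999), and osteoblast transcription factors for undifferentiated C/EBPβ (0.0384) and differentiated RUNX2 (0.0483).

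H3K4me3 regions covered 51.3 Mb in undifferentiated and 22.2 Mb in differentiated cells while their number rose. Joining or widening by the region calling has the values it requires: 97.0% of undifferentiated regions overlapped a differentiated region, and the median width of shared regions was 2.19 times larger in undifferentiated cells (5317 against 2433 bp). A biological spread of the mark beyond promoters in undifferentiated cells would give the same values and remains open, as does a difference in depth, which the lists leave unknown.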
